A study of Rattus norvegicus with 15 samples.

How the data were processed

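Expression was measured with single-channel oligonucleotide arrays in 15 samples of rat midbrain, 8 of the substantia nigra pars compacta (SNc) and 7 of the ventral tegmental area (VTA). Per the labels, the samples came from 8 control rats numbered 1 to 8, and each of 7 rats (all but rat 7) gave a sample of both regions. The series title names dopaminergic neurons as the cells compared. How the cells or tissue were collected, amplified and labelled is not given in the sources used here.

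The deposited values are linear intensity values, 1 per probe set and array, for 8799 probe sets. Per the values, the authors had scaled each array: the mean after trimming 2% at each end lay between 150.186 and 150.222 units on the 15 arrays, while the quartiles differed. The software that summarized the probes and its version are not given in the sources used here. The table holds no detection calls, so presence or absence of a transcript cannot be read from it. A value is the brightness of 1 probe set, and levels of different probe sets are not comparable with each other. Because each array was scaled to the same trimmed mean, a difference in total RNA between the regions cannot be seen in these values. The number of arrays limits the precision. No columns were left unused.

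Since the arrays were already scaled, the intensity values were used as deposited and transformed as log2(value + 16). The pseudocount of 16 shrinks differences of dim probe sets, so folds are on the log2(value + 16) scale and understate changes of low signals. After removal of 59 control probe sets, the 60% of the remaining 8740 probe sets with the highest mean log2 value over all arrays were tested, which left 5244 probe sets with a mean of at least 26.34 units (back from the log2 scale). The regions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with the rat as a fixed block and Benjamini-Hochberg adjustment. A probe set with an adjusted p under 0.05 was called. The 7 rats with both regions entered this fit (14 arrays), and all means and standard deviations are over these 7 rats. The SNc sample of rat 7 has no partner. It entered the filter, the choice of 1 probe set per gene, quantile normalization, median centring and the fits without the block or with a random block. It also entered the array correlations and principal components, the search for values that stood apart, the Gad1 to Pvalb correlation and the test on rat 7. Differences are SNc minus VTA throughout.

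The pairing comes from the labels, which give the same animal for both regions. The deviations of the paired arrays from their region means correlated at 0.044 to 0.254 (median 0.111, across probe sets), against a median of -0.026 between arrays of different rats. In 3 of the 7 rats the SNc array correlated best with the VTA array of its own rat. No pair of arrays had identical values, and correlations between arrays were 0.89 to 0.965.

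Gene symbols came from the platform annotation given with the series. Of the 8740 probe sets, 7006 had 1 gene symbol, 308 had several and 1426 were not listed, and only those with 1 symbol were named. They stand for 4736 genes, of which 3221 had a tested probe set. The entrez identifiers of 6994 probe sets with 1 symbol were found in the gene table of rat assembly GRCr8, and 0 of these symbols changed. No genome build is named for the array, so no coordinates are given. Named genes followed a rule fixed before the data were examined. It took the 12 genes with the largest difference in each direction among called probe sets with the same direction in at least 6 of 7 rats, with symbols that are only locus codes skipped. It added up to 4 members with the smallest p from each gene list, and a fixed set of dopamine neuron and region genes (Th, Slc6a3, Slc18a2, Ddc, Drd2, Nr4a2, Kcnj6, Aldh1a1, Calb1, Lpl, Nrp1, Adcyap1, Sox6 and Otx2) where measured. Sox6 and Otx2 had no probe set with 1 symbol, and the probe set of Kcnj6 lay below the filter.

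The 29 gene lists (899 entries, 616 on the array) were written before the data were examined. For each, 1 probe set per gene was used, the one with the highest mean log2 value over all arrays, so a gene called only at another probe set counts as not passed in its list. The 25 lists with at least 5 measured members were tested with limma's camera (two-sided, preset inter-gene correlation of 0.01, same blocked fit), adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. Camera tests a list against the other genes, while fry tests it against no change, so their p-values answer different questions. The lists named SNc literature and VTA literature came from general knowledge of midbrain dopamine neurons, part of which may come from this study, so their direction is not independent evidence.

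The pipeline was tested on simulated data. Arrays were drawn for the 5244 probe sets with the rat effects and spread of the real ones, and 200 probe sets were changed. For the SNc minus VTA comparison it recovered 20.9% of changes of 0.5 on the log2 scale, 89.6% of changes of 1 and 100% of changes of 2, and 4.8% of its calls were false. One simulated list raised by 0.5 among 25 was called, with 0 other lists called. Genes were drawn independently there, while those of real lists can vary together (estimated correlation 0.20 for glycolysis and the TCA cycle). The simulation thus does not show how often lists are called falsely in these data. The smallest p that an exact sign-flip permutation over 7 rats can give is 0.01562.

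Alternatives fixed before the data were examined were fits without the block or with a random block, quantile normalization, centring each array on its median, no filter, the highest 40% of probe sets, pseudocounts of 1 and 64, no variance trend, array weights, an exact sign-flip permutation for named genes, each rat left out in turn, and, for lists, the mean of a gene's probe sets, an estimated correlation and fry. A fit without rats 5 and 8 was added after seeing the data.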

Results

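Gene expression in the substantia nigra pars compacta (SNc) was compared with that in the ventral tegmental area (VTA), the neighbouring midbrain region that also holds dopamine neurons. The series title puts the comparison between the dopaminergic neurons of these regions. The data were 15 arrays from 8 control rats, 8 of SNc and 7 of VTA, and 7 rats contributed both regions. The median signal of an array was 37.95 to 46.7 units and the lower quartile was 8.665 to 13.97 units, so mean signals near 10 to 20 units lie close to the dim end of the arrays. Signals below are means ± SD over the 7 paired rats (n = 7), and differences are in log2(signal + 16).

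SNc and VTA differed at 155 of 5244 probe sets, 80 higher in SNc and 75 higher in VTA (limma with the rat as a block, adjusted p under 0.05). The probe sets higher in SNc represented 67 named genes and those higher in VTA 58. The median difference of the called probe sets was 0.72 toward SNc and -0.93 toward VTA, and 20 and 33 of them exceeded a difference of 1. All 155 had the same direction in at least 6 of the 7 rats, and 65 and 62 had it in all 7. The calls were made on these same rats, which favours such agreement, so it is not separate evidence. The probe sets higher in SNc had a median signal of 403 units and those higher in VTA 119 units. Without the rat as a replicate block, over all 15 arrays, 52 probe sets were higher in SNc and 61 in VTA. Centring each array on its median moved the median difference of all probe sets by 0.10 and the split to 164 against 56. The log2 median signal of the arrays was lower in SNc in 6 of the 7 rats (mean difference -0.14, exact sign-flip p = 0.078). The counts also depended on single rats. Without rat 1, 2, 3, 4 or 6 the fit called 52, 46, 37, 43 and 47 probe sets higher in SNc and 44, 44, 35, 41 and 43 higher in VTA, and without rat 5 it called 98 and 116.

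The named genes with the largest differences toward SNc were a phosphoprotein of the cAMP pathway (Arpp21), the growth factor Igf1 and the muscle-type enolase Eno3. Arpp21 had a signal of 161 ± 84.0 in SNc and 13.6 ± 15.8 in VTA, near the dim end of the arrays (log2 difference 2.59 ± 0.25 SE, adjusted p = 8.684e-05). Igf1 was at 277 ± 136.1 in SNc and 62.4 ± 47.1 in VTA (2.07 ± 0.31, adjusted p = 0.0026). Eno3, a glycolytic enzyme, was at 181 ± 68.9 and 32.2 ± 19.2 (2.05 ± 0.32, adjusted p = 0.0030). The protein kinase Prkcd differed by 1.88 and the membrane protein gene Pmepa1 by 1.87. Pmepa1 combined a high signal, 2817 ± 489 in SNc and 764.5 ± 173 in VTA, with the smallest adjusted p of these genes (1.13e-05). Tango2 (1.69), the GABA-synthesizing enzyme Gad1 (1.43), the plasma membrane calcium pump Atp2b2 (1.41), the calcium-binding protein Pvalb (1.28), Fbxo21 (1.19), the vesicle GTPase Rab3c (1.19) and the heavy neurofilament Nefh (1.11) followed. Among these 12 genes, the direction held in 7 of 7 rats for all but Rab3c, which held it in 6. Over the alternatives the difference ranged from 1.48 to 3.94 for Arpp21, 1.32 to 2.63 for Eno3 and 1.77 to 1.98 for Pmepa1. The order of these genes thus depends on the processing. The call on Pvalb was lost without rat 2 or rat 4 and with no filter (adjusted p up to 0.0622), and that on Rab3c (adjusted p = 0.04998) in 10 of 19 alternatives (up to 0.1296). Probe sets of a gene did not always move together. A further probe set of Arpp21 differed by -0.06 (adjusted p = 0.888), those of Igf1 by -0.22 and -0.32 (0.649 and 0.303), and those of Atp2b2 by 0.43 and -0.37 (0.146 and 0.367). A dimmer probe set of Nefh differed by 0.15 without passing (0.782). A brighter probe set of Tango2 (489 in SNc and 325.5 in VTA) differed by only 0.54 (0.0559) and a dimmer one of Rab3c by 0.87 (0.0672), neither past the threshold. Of the 125 genes with a call, 58 had several tested probe sets; all were called in 10 genes and their signs differed in 10.

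At the pseudocount of 16, the largest difference of any tested probe set was toward VTA, at M31176mRNA#2_at, which the annotation used here does not name (36.4 ± 13.1 in SNc and 357.5 ± 142 in VTA, log2 difference -2.79, adjusted p = 1.13e-05). Among named genes, Fst, which encodes the activin-binding protein follistatin, was at 9.995 ± 3.95 in SNc and 110.4 ± 49.4 in VTA (-2.18 ± 0.25, adjusted p = 4.063e-04). Crhbp, which encodes a binding protein of corticotropin-releasing hormone, was at 106 ± 56.9 in SNc and 423 ± 140.6 in VTA (-1.97 ± 0.28, adjusted p = 0.0020), with a further probe set at -1.86. The hormone itself (Crh) was at 20.4 ± 17.6 and 77.6 ± 35.2 (-1.32, adjusted p = 0.0124). The adrenergic receptor Adrb3 (-1.72), the inward rectifier potassium channel Kcnj5 (-1.57), the serotonin receptor Htr7 (-1.53) and the bradykinin receptor Bdkrb1 (-1.34) were also higher in VTA. The neuropeptide Adcyap1 differed by -1.43 and -1.17 at 2 probe sets (adjusted p = 0.0074 and 0.0026), while its brightest probe set differed by -0.52 without passing the threshold (adjusted p = 0.116). The neurotrophin Ntf3 was at 246 ± 79.4 in SNc and 632 ± 128 in VTA (-1.35, adjusted p = 0.0011). Cyclin Ccnd2 (-1.44), the complement inhibitor Serping1 (-1.40) and Gch1 (-1.33) completed the 12 genes. Adrb3, Ccnd2 and Crh had the direction in 6 of 7 rats and the others in 7. The call on Adrb3 was lost without rat 1 (adjusted p = 0.0525) and that on Serping1 without rat 2 or rat 6 and with no filter (up to 0.0616). SNc signals of Fst, Htr7 (15.9 ± 14.03) and Bdkrb1 (17.2 ± 4.35) lay near the dim end of the arrays. Further probe sets of Ccnd2 (-0.83, adjusted p = 0.0601) and Bdkrb1 (-0.57, adjusted p = 0.149) did not pass. Over the alternatives the difference ranged from -3.25 to -1.18 for Fst and from -2.25 to -1.54 for Crhbp, so their order depends on the processing.

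**Figure D1:**
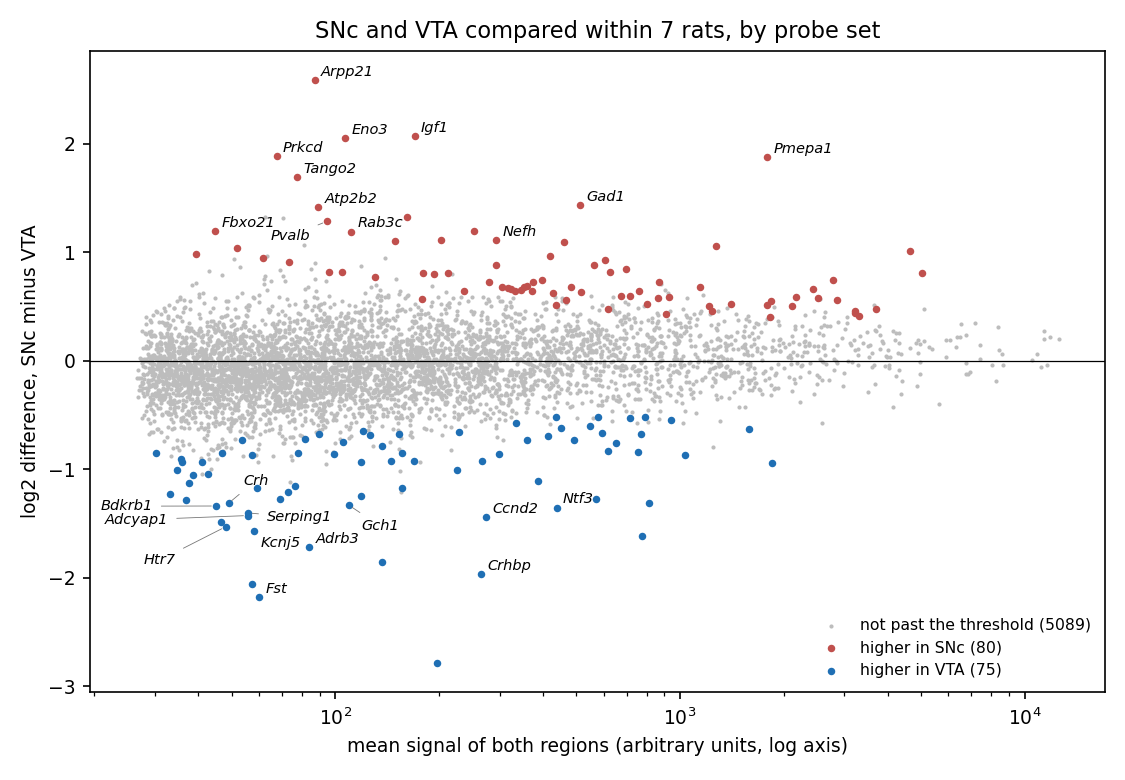
Log2 difference (SNc minus VTA, of signal + 16) of each of the 5244 tested probe sets against the mean of the SNc and VTA signals (arbitrary units, log axis), over 7 rats. Red points are the 80 probe sets called higher in SNc, blue points the 75 called higher in VTA and grey points the rest; the 12 named genes with the largest differences in each direction are labelled, from Arpp21 at 2.59 to Fst at -2.18.

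Of 20 measured genes of the dopamine neuron list, Sncg and Gch1 differed between the regions and 18 did not pass. Tyrosine hydroxylase (Th) had a signal of 6673 ± 540 in SNc and 7193 ± 770 in VTA (-0.10, 95% interval -0.28 to 0.07), and the vesicular monoamine transporter Slc18a2 was at 3132 ± 1144 and 3031 ± 661 (-0.01, -0.25 to 0.24). The decarboxylase Ddc differed by 0.15 (-0.10 to 0.40), the receptor Drd2 by 0.07 (-0.30 to 0.44) and Aldh1a1 by 0.19 (-0.11 to 0.49), none past the threshold. The dopamine transporter Slc6a3 was at 7268 ± 647 in SNc and 5782 ± 979 in VTA (0.34, 0.14 to 0.54), with an adjusted p of 0.0672 and the direction in 6 of 7 rats. A dimmer Slc6a3 probe set, at 774 in SNc and 738 in VTA, differed by only 0.09 (adjusted p = 0.7715). The transcription factor Nr4a2 differed by -0.69 (-1.09 to -0.28, adjusted p = 0.0666), with the direction in 7 of 7 rats. Adjusted over the list alone, 2 members were higher in SNc and 2 higher in VTA, Slc6a3 and Nr4a2 among them, and the list did not pass as a set (adjusted p = 0.4003). The members that passed were Sncg, which encodes gamma-synuclein, at 1717 ± 391 in SNc and 823 ± 232 in VTA (1.06, adjusted p = 7.894e-04), and Gch1, the first enzyme of tetrahydrobiopterin synthesis, at 476 ± 178 and 1153 ± 291 (-1.31, adjusted p = 7.894e-04). A further Gch1 probe set was at -0.65 without passing (adjusted p = 0.0814).

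**Figure D2:**
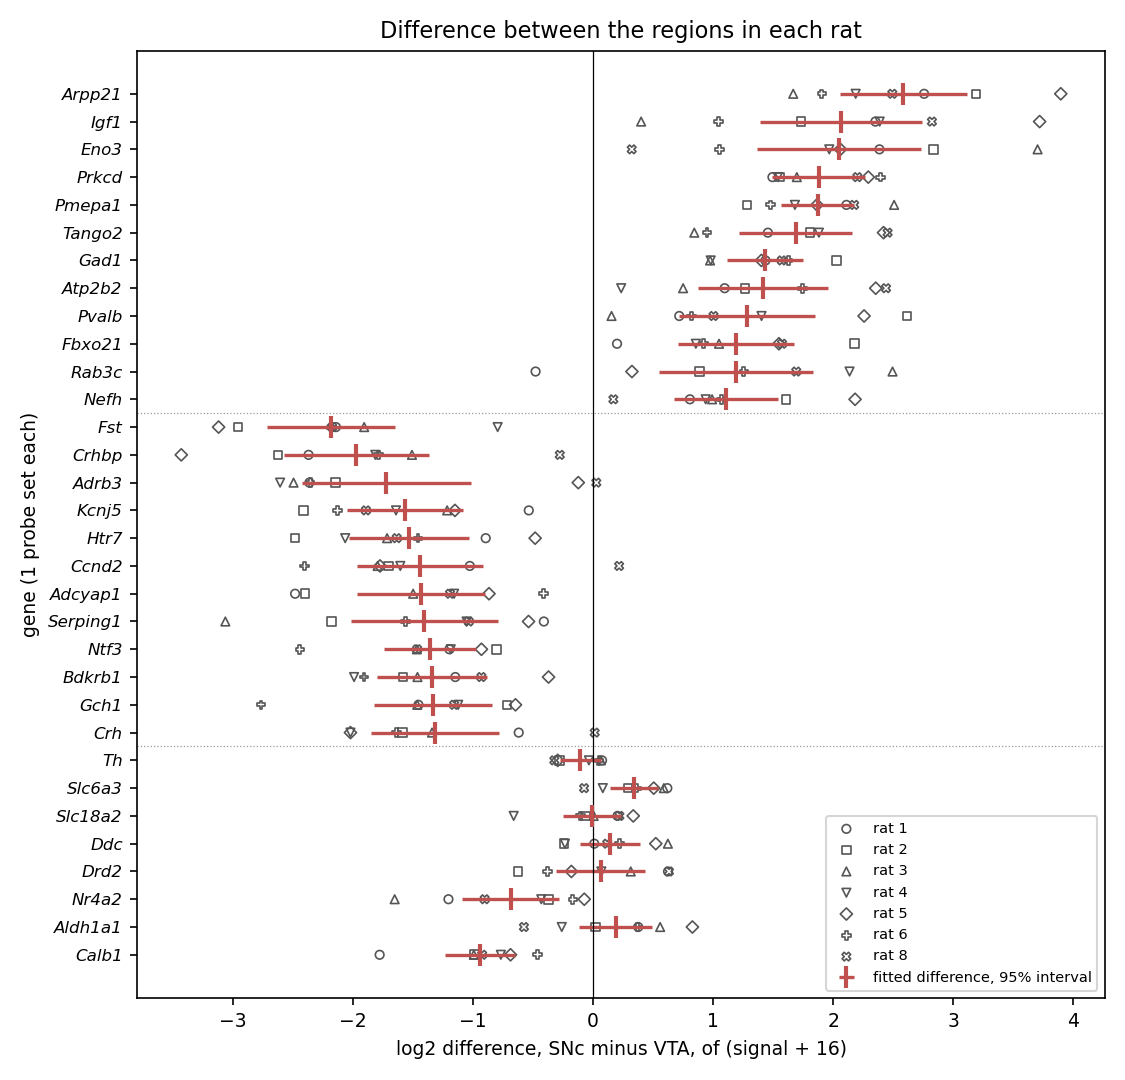
Log2 difference (SNc minus VTA, of signal + 16) in each of the 7 rats, 1 symbol per rat, for the 12 named genes with the largest differences in each direction and for 8 dopamine neuron and region genes; the red bar is the fitted difference with its 95% interval. Gad1 lies above 0 and Calb1 below 0 in all 7 rats, while Th (-0.10) and Slc18a2 (-0.01) scatter around 0.

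Glycolysis and TCA cycle genes lay mostly toward SNc. Of 24 measured genes of glycolysis and the TCA cycle, 21 had a positive difference, 3 were called higher in SNc, 0 higher in VTA and 21 did not pass (7 and 0 when adjusted over the list alone). The median was 0.23, positive in 6 of 7 rats. The list passed with camera (adjusted p = 2.581e-06) but not with an estimated correlation (adjusted p = 0.2585 with an estimated correlation). Lactate dehydrogenase B (Ldhb) was at 6409 ± 791 in SNc and 3677 ± 586 in VTA (0.81 ± 0.10, adjusted p = 0.0011), pyruvate kinase Pkm at 3000 ± 697 and 1863 ± 302 (0.66, adjusted p = 0.0102), and the pyruvate dehydrogenase subunit Pdha1 at 1045 ± 80.2 and 774.8 ± 75.9 (0.43, adjusted p = 0.0391). Of 10 ATP synthase genes, 1 was higher in SNc (Atp5pf, 0.45, adjusted p = 0.0359) and 9 did not pass (4 when adjusted over the list alone), and the median of 0.19 was positive in 7 of 7 rats. Of 16 genes of respiratory complexes II to IV, 0 passed on their own (1, Uqcrfs1 at 0.36, when adjusted over the list alone), and the median was 0.17. Both lists passed with camera (adjusted p = 0.0071 each), but not with an estimated correlation (adjusted p = 0.2585 each with an estimated correlation) nor after quantile normalization (adjusted p = 0.123 each). Complex I (24 genes, median 0.12) did not pass (adjusted p = 0.0972). It passed without rat 5 (0.0280), without rats 5 and 8 (0.0211) and with array weights (0.0402). Differences rose with signal on these arrays: the median over all probe sets was -0.11 in the dimmest of 6 equal groups and 0.07 in the brightest, where most of these metabolic genes lie.

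The lists of region markers from the literature, which are not independent of this study, moved in their named directions by their medians, with some members opposed. The median was positive in 7 of 7 rats for SNc literature and negative in 6 of 7 for VTA literature (0.49 in rat 8). Of 11 measured members of the SNc literature list, 3 were higher in SNc and 8 did not pass. Adjusted over the list alone, 5 were higher in SNc and 1 was higher in VTA (list by camera, adjusted p = 0.0071, median 0.19; adjusted p = 0.2585 with an estimated correlation). The 3 genes were Igf1, the calcium pump Atp2a3 (0.88, adjusted p = 0.0194) and the fibroblast growth factor Fgf1 (0.77, adjusted p = 0.0352). The potassium channel subunit Kcns3 was at 0.80 (adjusted p = 0.0584). Agtr1a (-0.91, adjusted p = 0.101), Anxa1 (-0.46, adjusted p = 0.467) and Slc18a2 (-0.01) lay the other way without passing. Of 8 measured members of the VTA literature list, 3 were higher in VTA, 1 was higher in SNc and 4 did not pass. Adjusted over the list alone, 5 and 2 passed (list adjusted p = 0.0310, median -0.73; adjusted p = 0.2585 with an estimated correlation). The tachykinin receptor Tacr3 (242 ± 60.3 in SNc and 532 ± 83.0 in VTA, -1.11, adjusted p = 7.894e-04), the calcium-binding protein Calb1 (1267 ± 289 and 2440 ± 530.5, -0.94, adjusted p = 0.0020) and the actin-linked protein Marcks (-1.01, adjusted p = 0.0194) were higher in VTA. Calb2, another calcium-binding protein on that list, was higher in SNc (0.68, adjusted p = 0.0204). Cck, also on that list, lay toward SNc without passing (0.46, adjusted p = 0.209). The other Marcks probe sets were at -0.62, -0.05 and -0.03 without passing (adjusted p = 0.105, 0.919 and 0.974). Lipoprotein lipase (Lpl) was at 85.5 ± 58.9 in SNc and 225 ± 141.3 in VTA (-1.21) with an adjusted p of 0.0545, and Nrp1 differed by -0.18 (-0.87 to 0.52). The VTA list did not pass without rat 1 (0.0589) or rat 5 (0.173).

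Of 23 neuropeptide and granin genes, 3 were higher in VTA and 20 did not pass (6 higher in VTA and 1 in SNc when adjusted over the list alone; camera, adjusted p = 0.0372, median -0.18; adjusted p = 0.2585 with an estimated correlation). The granin Scg2 was at 1246 ± 224 in SNc and 1922 ± 260.5 in VTA (-0.63, adjusted p = 0.0061) and the granin-related Vgf at 110.0 ± 36.9 and 203 ± 29.2 (-0.85, adjusted p = 0.0127), beside Crh. Chromogranin B (Chgb) lay the other way without passing (0.48, adjusted p = 0.0503). Of 12 immediate early genes 0 passed on their own and 11 had a negative difference, among them Jun (-0.70, the only one that passed when adjusted over the list alone) and Fos (-0.39; list adjusted p = 0.0409, median -0.27; adjusted p = 0.4935 with an estimated correlation). A further, dimmer Fos probe set was at 0.36 without passing (adjusted p = 0.307). The peptide list did not pass without rat 2, 4 or 5 (0.0803, 0.0691 and 0.0743). The immediate early list did not pass without rat 1, 4, 6 or 8 (0.0516, 0.1363, 0.0686 and 0.0858) nor after quantile normalization (0.0722).

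Among calcium handling, channel, receptor, vesicle and growth factor genes, single genes passed while none of the lists did. Of 24 calcium buffering and pumping genes, 5 were higher in SNc and 1 was higher in VTA (7 and 2 when adjusted over the list alone; list adjusted p = 0.0972). The inositol trisphosphate receptor Itpr1 (797 ± 166 in SNc and 412 ± 92.4 in VTA, 0.93, adjusted p = 0.0073) and the pump Atp2a2 (0.58, adjusted p = 0.0084) were higher in SNc together with Atp2a3, Pvalb and Calb2, while Calb1 was higher in VTA. The other Atp2a2 probe sets were at 0.30, 0.33 and -0.38 without passing. Of 29 voltage-gated channel genes, the potassium channel Kcnc1 was higher in SNc (1.11, adjusted p = 0.0126) and the calcium channel subunit Cacna2d1 higher in VTA (-0.53, adjusted p = 0.0413), with 4 and 1 when adjusted over the list alone (list adjusted p = 0.0927). Of 50 transmitter receptor genes, the glutamate receptor subunit Gria1 was higher in SNc (0.81, adjusted p = 0.0181), and Tacr3, the adrenergic receptor Adra1b (-0.93, adjusted p = 0.0198) and the glutamate receptor subunit Grin2a (-0.75, adjusted p = 0.0287) were higher in VTA, with 1 and 5 when adjusted over the list alone (list adjusted p = 0.2211). Of 24 vesicle release genes, Synj1 (0.58, adjusted p = 0.0131), Vamp2 (0.47, adjusted p = 0.0497) and Rab3c were higher in SNc and 0 higher in VTA (5 and 0 when adjusted over the list alone; list adjusted p = 0.0956). Growth factor genes split, with Igf1 and Fgf1 higher in SNc and Ntf3 and the binding protein Igfbp3 (-1.21, adjusted p = 0.0204) higher in VTA (2 and 6 of 23 when adjusted over the list alone; list adjusted p = 0.0621, and 0.0360 without rat 8). At probe sets other than the brightest, which alone are counted in the lists, Syn2 (0.95) and Grin2c (1.10) were also called higher in SNc and Gabbr1 (-1.28) higher in VTA. Other probe sets of Vamp2 (0.03, adjusted p = 0.950) and Igfbp3 (-0.26, 0.695) did not pass. Neither did those of Gria1 (0.64 and 0.14, 0.0559 and 0.734) and Synj1 (0.52, 0.0766). None of these 5 lists passed with an estimated correlation, where the smallest adjusted p was 0.2585.

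Markers of other cell types were measured beside these genes. Of the 4 measured GABA neuron markers, too few to test as a list, Gad1 (746 ± 193 in SNc and 279 ± 123.1 in VTA, adjusted p = 1.551e-04) and Pvalb (135.0 ± 47.4 and 53.7 ± 38.01) were higher in SNc, while Gad2 (0.18, -0.28 to 0.65) and the vesicular GABA transporter Slc32a1 (385 ± 122.2 and 374 ± 67.5, 0.00, -0.31 to 0.32) did not pass. A dimmer Slc32a1 probe set was at -0.35 without passing (adjusted p = 0.264). Oligodendrocyte genes had a median of -0.19 (10 genes, 0 called, adjusted p = 0.0972), with Mobp at -0.57 and Mbp, at 3906 ± 896 in SNc and 4838 ± 983 in VTA, at -0.31. The list passed after quantile normalization (0.0406) and without rat 6 (0.0331). Astrocyte genes (13, median -0.01, positive after median centring, adjusted p = 0.7897), microglial genes (5, adjusted p = 0.7897) and vessel genes (10, adjusted p = 0.6759) did not pass as lists; 1 astrocyte gene, Ntsr2, was higher in SNc (0.67, adjusted p = 0.0391). The 4 measured serotonin and noradrenaline neuron genes (Fev at -0.48, Slc6a4 at -0.28, Slc6a2 at -0.26 and Pnmt at -0.02), the 3 blood genes (Hbb at -0.73, Alas2 at -0.38 and Slc4a1 at 0.02) and the glutamate neuron gene Neurod2 (0.48) did not pass. Adjusted over the list alone, Fev passed toward VTA (adjusted p = 0.0338), with the direction in 7 of 7 rats, and so did Neurod2 toward SNc, as the single measured gene of its list (0.0423).

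**Figure D3:**
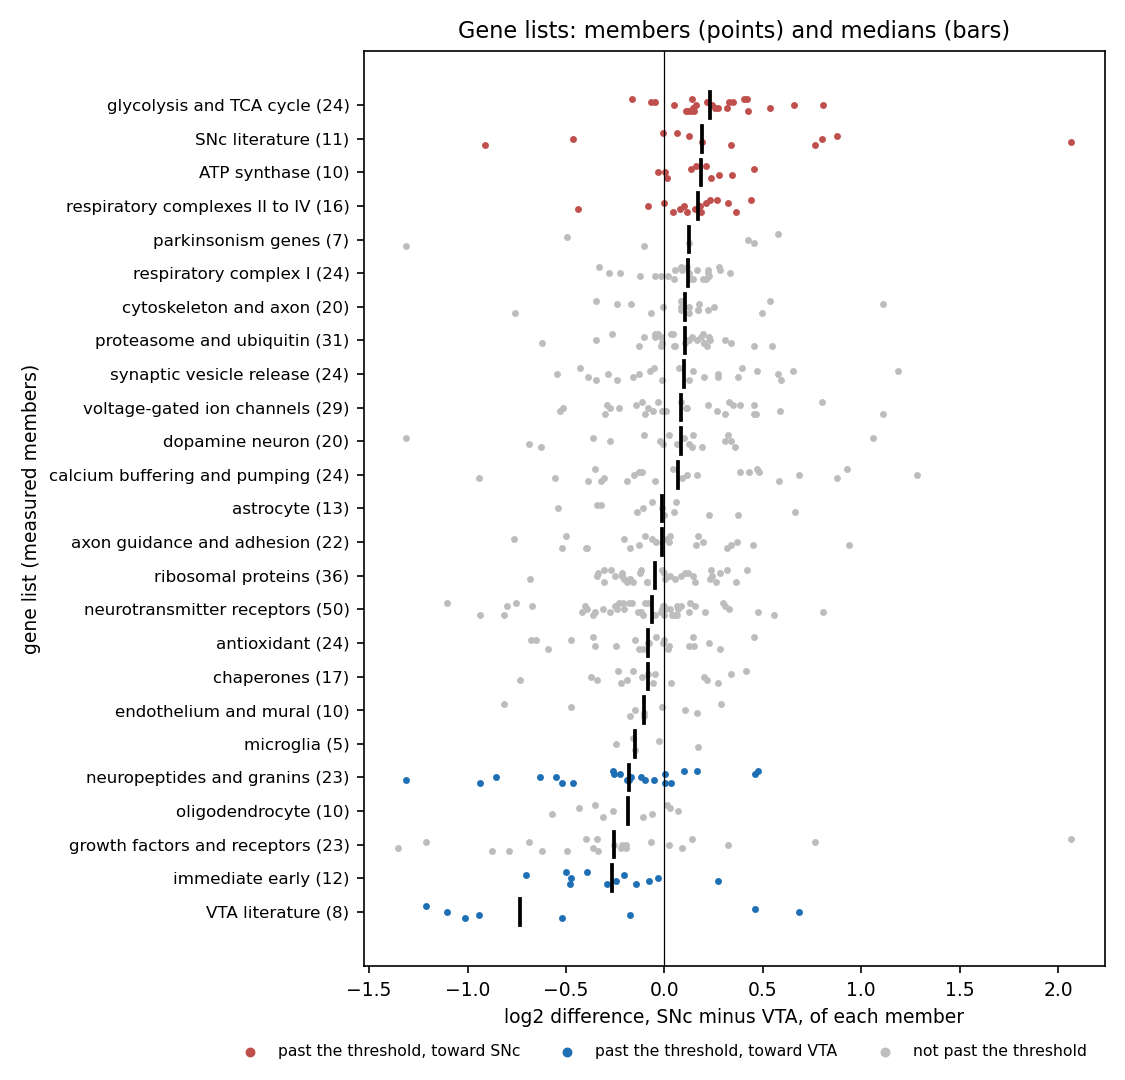
Log2 difference (SNc minus VTA, of signal + 16) of each measured member (points) and the median (bars) of the 25 tested gene lists, with the number of measured members in brackets, over 7 rats. Red and blue lists passed with camera toward SNc (4 lists) and toward VTA (3 lists), and grey lists did not; 0 lists passed with an estimated correlation.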

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

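Of the tests in this part, those on signal-dependent differences, on RNA integrity and on the other GABA markers were chosen after the results they bear on had been seen; the label swaps and the Gad1 to Pvalb correlation were set before.

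One array stood apart from the rest of its region, by the gap to its nearest neighbour, in 19 of 256 groups of named-gene values, where chance gives about 12.8 (1 in 20). Among the genes with the largest differences, low values stood out for Crhbp in SNc of rat 5 (13.3 units, next 70.8), Gch1 in SNc of rat 6 (6.82 at its dimmer probe set, next 43.0), Ccnd2 in VTA of rat 8 (166.8, next 380) and Crh in VTA of rat 8 (9.41, next 51.45). A high value stood out for Crh in SNc of rat 1 (59.25, next 22.3) and for the brighter Gch1 probe set in VTA of rat 8 (1793, next 1137). In VTA of rat 5, Cntn6 (3.62), Hspb1 (320.2) and Kcns3 (44.3) were low and Ndufc2 (2872) was high. In SNc of rat 4, Rpl6 (883) and Cplx2 (221) were low and Vamp2 (1125) was high. In VTA of rat 4, Ndufs6 (798) was low and Calb2 (1377) was high, and in VTA of rat 3 Slc6a2 (53.1) was low and Ugt8 (1203) was high. Adra1b was low in SNc of rat 3 (27.0), and Atp5pb was low in the unpaired SNc sample of rat 7 (687.7, against a median of 1823).

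The 155 calls were set against the splits that swap the region labels within rats. Of 64 splits, 1 (the real one) gave as many, and the highest of the others gave 8. This is the smallest share that 64 splits can give, so chance is unlikely for the number of probe sets but not excluded. The 7 lists called were reached by 3 of the 64 splits, the real one included. The highest of the others also gave 7, in the splits that swapped rat 6 alone or rat 8 alone. The share is under 0.05, but narrowly. Single-rat swaps keep most of the real arrangement, but swaps of more rats also called lists. Swapping rats 6 and 8 gave 6 lists, rats 4, 6 and 8 gave 6, and rats 5, 6 and 8 gave 5, while rats 2 and 3 gave 0. Camera with the preset correlation thus calls lists under swapped labels too, which limits what the 7 list calls show.

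The shift of 3 lists of metabolic genes toward SNc could come from the arrays, since bright probe sets differed toward SNc in general, but among 10000 random lists matched on mean signal, a share of 0.0014 had a median as high as that of glycolysis and the TCA cycle, and this list kept its call after quantile normalization (adjusted p = 3.164e-04), which argues against the signal trend as the whole cause. For complexes II to IV and ATP synthase the shares were 0.0536 and 0.1105 and the calls were lost after quantile normalization, so the trend remains a candidate explanation there. Unequal RNA integrity stays open for glycolysis: over the 7 rats its median correlated with the region difference in the 3' to 5' signal ratio of beta-actin at r = 0.502 (exact permutation p = 0.252, rho = 0.75 with exact p = 0.0663) and of GAPDH at r = 0.386 (exact p = 0.425, rho = 0.214 with exact p = 0.662; 2 relations tested), and without the 2 rats farthest from the median r was 0.218 and -0.542. The ratios differed between the regions without passing the threshold (beta-actin 0.22, higher in SNc in 4 of 7 rats, exact p = 0.2031; GAPDH -0.05, higher in 3, exact p = 0.5625), while the list median was positive in 6. A difference between the neurons of the regions stays open too, untested, and matched random lists ignore that genes of a list vary together.

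The higher Gad1 signal in SNc may reflect GABA neurons collected with the SNc cells, or Gad1 transcripts in the dopamine neurons themselves. The other 3 measured GABA neuron markers had a median difference of 0.18, with Pvalb at 1.28 and Slc32a1 at 0.00. A dimmer Slc32a1 probe set was lower in SNc in 6 of 7 rats without passing (-0.35, adjusted p = 0.264), opposite to Gad1. The markers do not move as a set and do not settle it. Over the 8 SNc arrays Gad1 and Pvalb correlated at r = 0.513 (exact permutation p = 0.189, rho = 0.548 with exact p = 0.171; 1 relation tested), and r was 0.137 without the 2 arrays farthest from the Gad1 median. These explanations cannot be told apart here, since few markers of the list were measured and they disagreed. Slc32a1 did not share the rise of Gad1 (interval -0.31 to 0.32), with 374 units in VTA against 279 for Gad1. How far its probe set would follow a share of GABA cells is not known. Whether other genes higher in SNc, such as Kcnc1 (1.11) and Nefh (1.11), come from the same cells as Gad1 was not tested.

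In the dimmest 2 of 6 equal signal groups, 26 probe sets were called higher in VTA against 7 higher in SNc. The signal trend could produce such an excess. After quantile normalization, 19 were called higher in VTA and 10 higher in SNc in this range, so the excess shrank but remained. The median difference of the 26 went from -1.22 (SD 0.36) to -1.14 (SD 0.37). That of all probe sets in the dimmest group went from -0.11 to -0.01. The trend was thus small beside these differences, though the 26 were selected as calls, which favours large differences. Their median SE went from 0.233 to 0.221, so more noise does not account for the lost calls. The smaller excess goes in the direction of the trend. Whether the trend tipped calls near the threshold stays open, as do differences between the regions, including cells of other types in VTA samples.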

How the results depend on the processing

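The fit without rats 5 and 8 was chosen after seeing the data; the other alternatives were fixed before. Arrays of these rats stood apart on principal components: both arrays of rat 8 lay at 19.08 and 18.95 (SNc, VTA) on component 3, and the SNc arrays of rats 5, 7 and 8 at 0.042, 1.145 and 3.97 on component 1, against -19.8 to -12.3 for the other SNc arrays. No list or named probe set that passed in the paired fit turned its direction in these alternatives. Of the lists that did not pass, the astrocyte, microglia, vessel, ribosomal protein, chaperone and axon guidance lists turned theirs in some, without passing there. Of 54 named probe sets past the threshold, 41 to 54 stayed past it under the alternatives that kept all 7 rats and tested all of them, 36 to 51 with 1 rat left out, and 42 of the 42 tested among the highest 40% of probe sets. Without the replicate block 43 stayed. The exact sign-flip p, unadjusted, was under 0.05 for these 54 and for 38 others of the 128 named probe sets, so it says nothing about stability. Low signals limit the dim probe sets most, since the table has no measure of signal over background.

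The count of probe sets higher in SNc (80) was 52 with no replicate block, 164 with median centring, 41 with no trend and 145 with array weights, and 37 to 98 with 1 rat left out. The count higher in VTA (75) was 173 with array weights, 153 without rats 5 and 8 (120 higher in SNc), and 35 to 116 with 1 rat left out. Of the 80 and 75, 48 and 52 were shared with the fit without the block, and 70 and 62 with quantile normalization. The counts were lower without rat 1, 2, 3, 4 or 6 and higher without rat 5 or 8; the cause was not tested.

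With an estimated correlation the glycolysis, ATP synthase, complexes II to IV, SNc literature, VTA literature and peptide lists each had an adjusted p of 0.2585 and the immediate early list 0.4935. With fry, SNc literature (0.0604), complexes II to IV (0.0534) and immediate early (0.0817) no longer passed and vesicle release passed (0.0246). Quantile normalization ended the calls on ATP synthase and complexes II to IV (0.123 each) and immediate early genes (0.0722), and brought in oligodendrocyte (0.0406) and ribosomal protein genes (0.0492), both toward VTA. The peptide and immediate early lists did not pass with no filter (0.0605 each) or the highest 40% (0.0551 and 0.0697), nor immediate early genes with the mean of a gene's probe sets (0.1672). Proteasome genes (0.0594) passed with no replicate block (0.0451), median centring (0.0299), no filter (0.0204), array weights (0.0333) and without rats 5 and 8 (0.0211). Growth factors passed with no replicate block (0.0196), median centring (0.0299), array weights (0.0402) and without rats 5 and 8 (0.0380). Array weights also brought in complex I (0.0402) and channels (0.0406), as did leaving out rats 5 and 8 (0.0211 and 0.0432), without which the VTA literature (0.0729) and peptide lists (0.0911) did not pass. With 1 rat left out, adjusted p ranged from 0.0085 to 0.1727 for VTA literature, 0.01075 to 0.0803 for peptides, 0.01996 to 0.1363 for immediate early, 0.0331 to 0.3856 for oligodendrocyte, 0.0280 to 0.3466 for complex I, 0.0179 to 0.1305 for proteasome and 0.0360 to 0.1233 for growth factor genes. The causes were not tested.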

Other observations

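The test on the sample of rat 7 was set before its result was seen.

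Some lists not described above held single genes with clear differences. Among 7 parkinsonism genes, Synj1 and the ubiquitin hydrolase Uchl1 (3726 ± 594 in SNc and 2698 ± 325 in VTA, log2 difference 0.46, adjusted p = 0.0198) were higher in SNc and Gch1 was higher in VTA, with 4 not passing (3 and 2 passed when adjusted over the list alone); Park7 was at 0.43 (adjusted p = 0.0722) and the list did not pass (0.4364). Of 31 proteasome and ubiquitin genes, Uchl1 passed and 30 did not at their brightest probe set (2 higher in SNc when adjusted over the list alone; list adjusted p = 0.0594, median 0.10), with Psmc3 at 0.55 (adjusted p = 0.0672); without rat 8 the list passed (0.0179). Of 4 Psmd1 probe sets, the brightest was at 0.14 without passing, another passed (0.52, adjusted p = 0.0466) and 1 lay the other way (-0.31). Among 20 cytoskeletal genes the neurofilament subunits went apart at their brightest probe sets: Nefh was higher in SNc (401 ± 89.1 and 186 ± 69.2, 1.11, adjusted p = 0.0098) and Nefm higher in VTA (487 ± 126.1 in SNc and 819 ± 128 in VTA, -0.76, adjusted p = 0.0174), while Nefl was at -0.35 without passing (2 and 2 passed when adjusted over the list alone; list adjusted p = 0.0972). A dimmer Nefh probe set was at 0.15 without passing (adjusted p = 0.782), so the Nefh call rests on 1 probe set.

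Of 24 antioxidant genes, the glutathione peroxidase Gpx3 was higher in VTA (114 ± 25.8 in SNc and 191 ± 33.4 in VTA, -0.68, adjusted p = 0.0234) and 23 did not pass at their brightest probe set (1 higher in SNc and 4 in VTA when adjusted over the list alone), with Gpx4 at 0.46 (adjusted p = 0.0658); the list had an adjusted p of 0.4364. Catalase (Cat) was at -0.59 there (adjusted p = 0.0634) and passed at another probe set (-0.68, adjusted p = 0.0407), and Sod1 was at 0.14 there and passed toward VTA at another (-0.55, adjusted p = 0.0383). Of 17 chaperone genes, the small heat shock protein Hspb1 was higher in VTA at its brightest probe set (-0.73, adjusted p = 0.0194) and at another (-0.86, adjusted p = 0.0377), while those at -0.45 and 0.12 did not pass (2 genes higher in SNc and 1 in VTA when adjusted over the list alone; list adjusted p = 0.7897). Of 36 ribosomal protein genes, Rps15 was higher in VTA (-0.68, adjusted p = 0.0142) at 1 of its 3 probe sets, as the 1 gene past when adjusted over the list alone, and the list did not pass (0.7897). Of 22 axon guidance and adhesion genes 0 passed (1 higher in SNc when adjusted over the list alone; list adjusted p = 0.7652), with Nrxn3 at 0.45 (adjusted p = 0.0529). With an estimated correlation 0 of the 25 lists passed.

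The SNc sample of rat 7 took no part in the paired comparison and served to test whether the calls extend to another animal. It lay on the SNc side of the midpoint between the regions at 62.6% of the 155 called probe sets (97). When each paired rat was left out in turn and the calls were made from the other 6, its SNc array lay on the SNc side at 57.8% to 97.2% of them (median 85.6%) and its VTA array at 10% to 29.7% (median 16.7%). The value for rat 7 is within the range of the SNc arrays and above that of the VTA arrays, but near the lower end, as for the SNc arrays of rat 5 (57.9%) and rat 8 (57.8%). The result goes with calls that reflect the region beyond the 7 pairs. The SNc samples of rats 5, 7 and 8 carried the pattern less fully than the other SNc samples (85.6% to 97.2%). The arrays of these rats also had the highest top signals. These were 15631 to 18796 units in SNc, against 9747 to 14504 on the other SNc arrays. In VTA they were 22182 and 24105 units, against 9799 to 13285 (rat 7 has no VTA array). Whether the arrays or the animals account for this was not tested.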
